A study of Bombyx mori and Mus musculus with 24 samples.

How the data were processed

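The series held 24 libraries, 9 from mouse testis and 15 from silkworm BmN4 cells, with the groups taken from the titles of the samples. Per the labels, RNA was extracted with phenol and chloroform, separated on urea polyacrylamide gels and made into libraries with a commercial small RNA kit. The deposited tables held counts, the raw number of reads of each distinct sequence per library, and no normalization had been applied to them. Each table listed all sequences of a sequencing pool with 1 genome position and 1 annotation name per sequence, and the lengths of the sequences matched their position spans. The submitters' processing notes name CASAVA and the mouse build mm9 for all samples, silkworm included, while the silkworm positions belong to a silkworm assembly that these notes do not name. The aligner, the mismatches allowed, the treatment of reads with several positions and the adapter trimming are not given in the sources used here.

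Small RNA libraries held 2032783 to 7896223 reads (mouse 3466570 to 7896223, silkworm small RNA 2032783 to 6319304), and the polyA+ libraries 138557162 (control) and 119561195 (GA) reads of 50 to 51 nt from 2 sequencing runs each. At these depths the counting error of most shares is small. Shares carry 95% Wilson intervals, differences of shares the interval of the difference, and log2 ratios the interval from the counts. These cover counting error only, so spread between animals or cultures is unknown wherever a group held 1 library. The 2 by-product libraries are given singly and as mean and SD.

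Lengths were grouped into 16 nt (by-product), 21 to 23 nt (miRNA size), 24 to 30 nt (piRNA class), 25 to 27 nt (Mili size) and 28 to 30 nt (Miwi2 size). The share of piRNA-class reads beginning with U, and the share with A at nucleotide 10, were counted over reads. Ping-pong complementarity was the number of pairs of distinct piRNA-class sequences whose first 10 nt were complementary, divided by the mean over 14 shifted placements of the same 10 nt (overlaps of 11 to 24 nt), with the distance from that mean in SD of the shifted counts. By-product placement was the share of distinct 16-nt sequences whose exact complement lay at nucleotides 11 to 26 of a piRNA of the Ago3 control library, set beside the same share at the 10 other starts. Annotation names were sorted into IAP, other LTR, L1, SINE and structural RNA groups in mouse and LTR, LINE, DNA, SINE, tRNA and gene model groups in silkworm. Names that matched none of these formed a group of other names, which in silkworm held piggyBac. Names were compared only within a pool, because pools named the same elements in different ways, and a name was compared when it held at least 0.5% of piRNA-class reads in either library. Shared sequences were the share of piRNA-class reads whose exact sequence was present in the other library.

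PolyA+ reads were summed per annotation name and scaled to the annotated reads of each library (99383345 and 77467045), with a prior of 0.5 read in log2 ratios. Transposon classes were compared with 10000 random lists of gene models of the same size, matched on mean expression in 20 bins, using names with at least 20 reads. The strand of most reads of a gene model, and of each 20-nt stretch of a transposon, was fixed on run 1 of the control library, and the shares on the other strand were taken from run 2 of the control library and from both runs of the GA library. Reads were also searched for exact 24-nt stretches of Siwi and Ago3 control piRNAs on either strand.

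Items named singly followed a rule fixed before the data were examined, as were the size classes, the measures and most alternatives. The rule took the 3 most abundant 16-nt sequences of each by-product library, the 3 most abundant piRNAs of Siwi control, Ago3 control and heterozygous Mili at postnatal day 0, the 10 most abundant miRNAs of the heterozygous total library, and the 10 largest rises and falls among gene models with at least 100 reads in the library where they were higher. It also took miRNAs known from liver, muscle, blood, neurons and gonad. Only some of these items are printed. Lists of chaperone, piRNA-pathway, proteasome, stress, detoxification, cell cycle, ribosomal and cytoskeletal genes had been planned, but 0 of 12525 gene model names were found in the reference name table, so these lists could not be tested and transposon classes were used in their place. Annotation names of repeats were named after their values were seen. Reads without an annotation, 28.3% of control and 35.2% of GA polyA+ reads, were not used in the counts of genes and transposons.

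The alternatives covered distinct sequences in place of reads, other size limits, sequences with at least 2 reads, other piRNA partners, thinning to equal depth, TMM scaling, DESeq2 size factors, a prior of 5 reads, other minimum counts, and stretches of 20 nt. Ping-pong pairs, by-product placement, gene changes, list percentiles and piRNA stretches were tested on simulated data. Of 2000 planted ping-pong pairs 1966 were found above the shifted mean, and the ratio with none planted was 1.05. The simulated sequences had random bases, without the U and A shares of the real piRNAs. The value of 1.05 is therefore not the ratio expected of the real libraries without ping-pong. All 500 planted by-product placements were found. Gene models with a simulated 4-fold change were all counted as at least 2-fold changed (100%), those with a 2-fold change in 44% of cases, and unchanged ones in 0%. The simulated counts varied by counting error only, with no spread between cultures, so the 0% does not bound false calls in the real libraries. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.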

Results

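Small RNAs bound by PIWI proteins were sequenced from mouse fetal and neonatal testis and from BmN4 cells, a silkworm ovary-derived line with a working piRNA pathway. PIWI proteins bind piRNAs, small RNAs that direct the cutting of transposon transcripts, and in the ping-pong cycle the cut of 1 RNA forms the start of the next piRNA. The 9 mouse libraries were Mili precipitates of Fkbp6 heterozygous and knockout testis at postnatal days 0 and 10, Mili precipitates of Tdrd1 heterozygous and knockout testis at embryonic day 18, a Miwi2 precipitate of the Tdrd1 heterozygote at that age, and total small RNA of 14 to 33 nt from Fkbp6 heterozygous and knockout testis at postnatal day 0. The 15 silkworm libraries held Siwi, Ago3 and HA-tagged Ago3 precipitates and polyA+ RNA, from control cells or cells treated with geldanamycin (GA), an inhibitor of the chaperone Hsp90, for 4 days, for 2 days with the HA-tagged constructs, and for 24 h before polyA+ RNA was taken. These libraries fell into 23 groups, and the by-product libraries of Ago3 after GA formed the only group with 2 libraries. Small RNA libraries held from 2032783 to 7896223 reads, and the polyA+ libraries held 138557162 reads (control) and 119561195 reads (GA). No other group had a replicate, so no test between groups was run, and each difference compares those libraries, not the conditions. Shares carry 95% Wilson intervals, which cover counting error only. These were PCR reads without molecular identifiers, so copies of 1 molecule were counted as separate reads. The intervals may therefore be too narrow even for counting error.

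The comparison of Siwi with Ago3 asked how the piRNAs of the silkworm ping-pong partners differed and whether GA changed them. Among reads of 24 to 30 nt, the piRNA class, Siwi piRNAs began with U in 83.9% of reads and Ago3 piRNAs in 35.5%, a difference of -48.5 points. Ago3 piRNAs carried A at nucleotide 10 in 85.5% of reads, and Siwi piRNAs in 38.8%, a difference of 46.7 points. Over distinct sequences these differences were -28.9 and 28.8 points. Siwi also held longer piRNAs, with 46.7% of reads at 28 to 30 nt against 16.9% in Ago3. After GA the A share at nucleotide 10 was 42.9% in Siwi and 81.9% in Ago3, and the share of reads of 28 to 30 nt was 39.8% in Siwi and 11.7% in Ago3. tRNA-annotated reads made up 0.295% of the Ago3 piRNA class in control cells and 0.991% after GA, 3.36-fold higher, but 0.193% and 0.233% of distinct sequences. In Siwi they went from 4.16% to 2.77% of reads, 1.502-fold lower, but stood at 0.187% and 0.190% of distinct sequences. Pairs of Siwi and Ago3 sequences whose first 10 nt were complementary occurred 3.68 times as often as the mean of 14 shifted placements in control cells, 16.7 SD of those placements above it. After GA the ratio was 3.58, at 17.8 SD. Weighted by reads, the ratios were 48.9 and 26.3. In these 10-nt pairs nucleotide 1 of each sequence faces nucleotide 10 of the other. The U and A shares above therefore enter the ratio, which was not corrected for them. Of Siwi control piRNA reads, 78.2% had a sequence also present in the Ago3 control library, and 69.0% of Ago3 control reads had one also present in Siwi, while of distinct sequences only 25.6% in Siwi and 23.4% in Ago3 were shared. The most abundant Siwi control piRNA, TCCCGTATGGTCTAGTGGCTAGGATACC (27189 reads, 0.95% of the class), was annotated as a glutamate tRNA. The most abundant Ago3 control piRNA, GGCTCAGTCAGCAACGATCGATCGCGC (30786 reads, 0.93%), was annotated as the Pao-type LTR element Yamato.

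The by-product libraries addressed what the 16-nt RNAs held by Ago3 after GA were. A PIWI protein cuts its target opposite nucleotides 10 and 11 of the guide piRNA, so a target fragment left on the protein should pair with the guide from nucleotide 11 on. Reads of 16 nt made up 89.6% of by-product library 1 and 40.3% of library 2 (mean 65.0%, SD 34.9, n = 2). In library 2, 52.7% of reads were under 15 nt, and 76.2% of those ended in the bases GATC followed by the barcode of that library. These short reads lower the 16-nt share of library 2 and widen the SD, since among reads of 15 nt and longer the share was 85.4%. Library 1 held 0 reads under 15 nt, and so did every library in its table, while the table of library 2 started at 9 nt. The shares of 89.6% and 40.3% were thus taken over unlike ranges of length. The complement of 22.6% of distinct 16-nt sequences in library 1 (95% interval 22.4 to 22.8%) and 24.4% in library 2 (24.1 to 24.7%) lay at nucleotides 11 to 26 of an Ago3 control piRNA (mean 23.5%, SD 1.25, n = 2). No other of the 10 alternative starts exceeded 9.48% in library 1 or 9.73% in library 2. Weighted by reads the placement held for 67.7% and 64.2% (mean 65.9%, SD 2.46, n = 2), against at most 22.7% and 22.6% at another start. Short RNAs of Ago3 from control cells, size-selected at 12 to 20 nt and sequenced apart from the GA libraries, showed the placement in 12.6% of distinct 16-nt sequences (12.5 to 12.8%), against at most 5.09% elsewhere. The few 16-nt sequences in the ordinary Ago3 precipitates showed it too, in 17.7% of sequences in control cells (14.9 to 20.9%) and 41.0% after GA (38.1 to 43.9%). Weighted by reads these shares were 6.64%, barely above the highest other start (6.26%), and 28.4%. Both Ago3 libraries, like the Siwi ones, shared the pool of by-product library 1, and carry-over from it was not tested. They held 2953 (control) and 2846 (GA) reads of 16 nt, beside 1821969 in by-product library 1. In Siwi precipitates the share was 10.8% of sequences in control cells and 9.80% after GA, against at most 7.87% and 8.35% elsewhere, but by reads the placement was not favoured, at 3.25% and 5.82% against 16.1% and 13.9% at the highest other start.

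Of 16-nt reads, LTR annotations held 19.4% in by-product library 1 and 22.5% in library 2, LINE annotations 14.2% and 15.3%, and gene models 8.42% and 8.51%. Other names, piggyBac among them, held 20.5% and 12.8%, while 33.7% and 36.5% had no annotation. The 2 libraries came from different pools, which named elements in different ways, so gaps between them may lie in the naming. The most abundant sequence in both by-product libraries, ACCAATCGGGCGTTGC, made up 4.85% of 16-nt reads in library 1 (88399 reads) and 2.54% in library 2 (21145 reads). It was placed on the plus strand of silkworm chromosome 5 at 20899203 to 20899218, annotated as a piggyBac DNA element, and its complement lay at nucleotides 11 to 26 of 4 Ago3 control piRNA sequences. The next in library 1, TATCAACGTGAACTTA on chromosome 16 (24130 reads, 1.32%), annotated as an element of unknown class, had such a partner, and ACACAGCGTGACACTT on chromosome 3, annotated as a gypsy-like LTR element (17483 reads, 0.96%), did not. The next in library 2, TAGATCTTTTGGATTT on chromosome 18 (13990 reads, 1.68%), had such a partner and no annotation. Of all 16-nt reads, 89.1% in library 1 and 92.8% in library 2 had a sequence also found in the other library. Across 1812 shared sequences with at least 200 reads over both, the median size of the log2 ratio of their shares was 1.07.

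**Figure D1:**
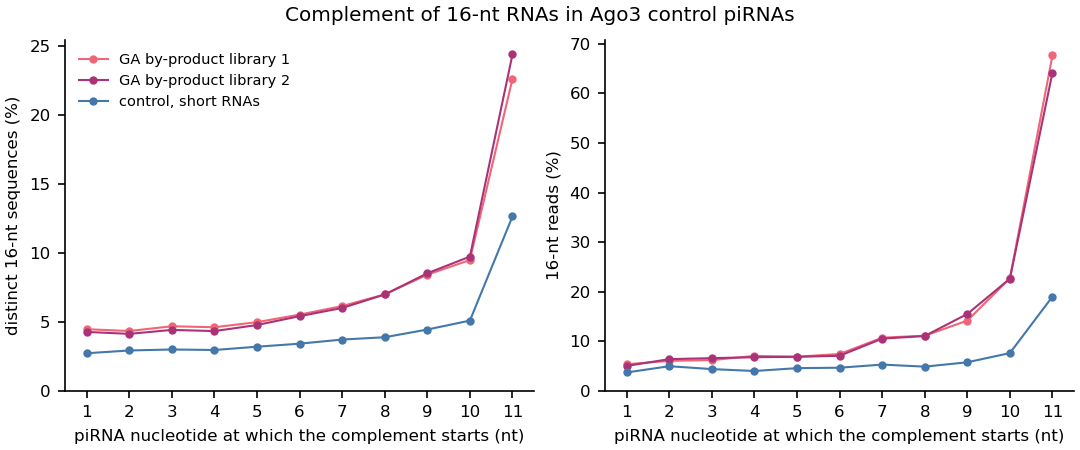
Percent of distinct 16-nt sequences (left) and of 16-nt reads (right) whose complement starts at each nucleotide from 1 to 11 of an Ago3 control piRNA, with 1 line for each GA by-product library and 1 for the control short RNAs. The share at nucleotide 11 was 22.6% and 24.4% of distinct sequences in the GA libraries and 12.6% in the control short RNAs.

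HA-tagged Ago3 constructs addressed whether the 16-nt fragments need Ago3 slicing and its arginines: wild type, the ADH construct, named for a change in the catalytic motif, and the R to K construct, in which arginines were replaced by lysines. In wild-type HA-Ago3, the share of distinct 16-nt sequences with their complement at nucleotides 11 to 26 was 9.74% in control cells (6.0 to 15.4%) and 30.6% after GA (27.7 to 33.6%), a difference of 20.9 points (14.5 to 25.7). The ADH construct showed 13.6% and 14.7%, a difference of 1.05 points (-3.43 to 5.38), and the R to K construct 8.33% and 4.68%, a difference of -3.66 points (-8.80 to 0.07). At the other starts the shares reached at most 10.3% in wild type after GA, 7.87% in ADH and 3.62% in R to K. These shares rest on 928 distinct 16-nt sequences in wild type after GA, 559 in ADH and 663 in R to K. Reads of 15 nt and 17 nt in wild type after GA showed the placement in 7.83% and 6.81% of sequences. The 16-nt share of all reads, which is blind to placement, was 2.69-fold higher after GA in wild type, 1.12-fold in ADH and 2.95-fold in R to K. The constructs were sequenced in different pools, ADH in that of by-product library 2, so construct and pool cannot be told apart, while control and GA of a construct shared 1 pool.

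**Figure D2:**
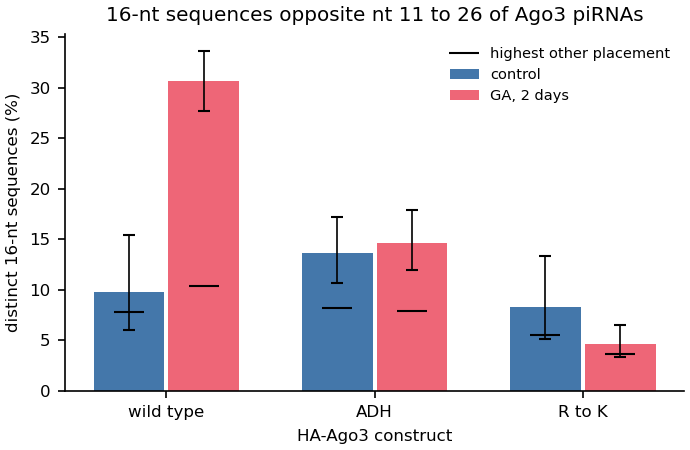
Percent of distinct 16-nt sequences of each HA-Ago3 construct, in control and GA-treated cells, whose complement lies at nucleotides 11 to 26 of an Ago3 control piRNA. Bars are single libraries with 95% Wilson intervals and short black lines mark the highest other start, and wild type after GA reached 30.6%.

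Among the piRNAs of wild-type HA-Ago3, those beginning with U went from 34.5% in control cells to 48.4% after GA. The change was 14.0 points, against 2.99 points in ADH and 1.96 points in R to K, where it turned to -0.39 points over distinct sequences. tRNA-annotated reads in wild type went from 7.42% to 15.3% of the piRNA class, with Asp(GTC) alone going from 3.53% to 14.5%, 4.12-fold higher, while Glu(CTC) and Glu(TTC) were 7.24-fold and 6.25-fold lower. Counted over distinct sequences, the tRNA share was instead lower after GA, by a log2 ratio of -0.34. The ADH construct held 6.25% and 6.37% tRNA-annotated reads and R to K 3.65% and 5.03%. Within-library ping-pong ratios were 2.93 and 3.51 in wild type, 1.94 and 1.97 in ADH, and 3.52 and 3.66 in R to K, control and GA in that order. Weighted by reads they were lower after GA in each construct, at 15.96 and 14.25, 7.04 and 6.87, and 22.06 and 19.74.

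The Fkbp6 comparisons asked how loss of this immunophilin-domain protein changed the piRNAs of Mili. In Mili at postnatal day 0, reads annotated to Fkbp6 itself numbered 501 in the heterozygote and 127 in the knockout, and such small RNAs check nothing about the genotype. IAP elements, a family of LTR retrotransposons, made up 3.17% of heterozygous piRNA reads (3.15 to 3.19%) and 11.9% in the knockout (11.8 to 11.9%), 3.75-fold higher (log2 1.91, 1.90 to 1.91). Other LTR elements went from 20.0% to 41.6%, 2.08-fold higher. SINE piRNAs were 2.41-fold lower, at 9.63% and 3.99%. LINE-1 (L1) piRNAs differed little, at 8.56% and 8.98%, and their direction turned when only sequences with at least 2 reads were counted (log2 -0.44). Of 32 annotations that held at least 0.5% of reads in either library, all 5 IAP names and 15 of 17 other LTR names were at least 2-fold higher, 4 of 5 SINE names were at least 2-fold lower, and none of 4 L1 names moved that far. The retroviral internal regions MMETn-int, RLTR4_MM-int, IAPEz-int, MMERVK10C-int and MERVL-int were 7.32-fold, 6.63-fold, 6.59-fold, 6.26-fold and 6.25-fold higher.

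Knockout Mili piRNAs at postnatal day 0 also had a different make-up. A at nucleotide 10 was present in 33.8% of heterozygous and 41.6% of knockout reads, a difference of 7.72 points (7.64 to 7.79), or 4.01 points over distinct sequences. U at the first nucleotide was present in 82.2% and 78.3%. Reads of 28 to 30 nt went from 13.1% to 20.1% of the library, 1.53-fold higher. Ping-pong pairs exceeded the shifted mean by similar ratios, 1.74 in the heterozygote and 1.84 in the knockout, or 2.66 and 3.95 when weighted by reads. Within groups the ratio was lower in the knockout for IAP (3.41 and 3.09), L1 (3.12 and 2.80) and SINE sequences (3.75 and 2.75) and higher for other LTR sequences (2.21 and 2.53). In SD of the shifted counts each of these groups went the other way. The distances were 9.09 and 9.51 for IAP, 13.2 and 15.9 for L1, 5.16 and 9.01 for SINE, and 9.93 and 8.11 for other LTR sequences. The group ratios were not thinned to equal depth. Of heterozygous piRNA reads, 30.4% had a sequence also found in the knockout, and 39.4% of knockout reads had one also found in the heterozygote. Depth limits such shares, since 1811004 of 2222559 distinct sequences of the heterozygous library had 1 read. No replicate shows what share to expect without a change. The B1_Mur4 piRNA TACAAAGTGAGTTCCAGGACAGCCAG, the third most abundant in the heterozygote, went from 2798 to 13 reads, and the L1Md_F2 piRNA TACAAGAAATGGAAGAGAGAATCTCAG from 3247 to 916. The most abundant sequence, a tRNA-Gly-GGA fragment (GCGTTGGTGGTATAGTGGTGAGCATA), went from 7732 to 5391. Each read carried 1 position and 1 annotation, so repeat families that share sequence cannot be separated further.

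At postnatal day 10 the largest Mili difference among repeat groups lay in L1, while SINE piRNAs were lower in the knockout at both ages. Fkbp6-annotated reads numbered 805 in the heterozygote and 790 in the knockout. L1 piRNAs went from 6.54% (6.52 to 6.57%) to 25.5% (25.4 to 25.5%), 3.89-fold higher (log2 1.96, 1.95 to 1.97), and 8 of 9 L1 names were at least 2-fold higher. L1Md_A was 11.1-fold, L1Md_F 7.54-fold and L1Md_T 6.58-fold higher. SINE piRNAs went from 19.5% to 9.62%, 2.03-fold lower, with 5 of 9 SINE names at least 2-fold lower and B1_Mur4 6.06-fold lower. Over distinct sequences the SINE difference nearly vanished, with a log2 ratio of -0.16. IAP piRNAs stood at 4.55% and 5.97%, 1.31-fold higher, and other LTR piRNAs at 8.26% and 7.57%. Counted over distinct sequences, the L1 difference was smaller, with a log2 ratio of 0.83. The ping-pong ratio was 3.71 in the heterozygote and 2.60 in the knockout (19.3 and 13.6 weighted by reads), and SINE sequences had ratios of 6.72 and 5.84 and L1 sequences 5.07 and 4.77, while other LTR sequences went the other way, at 3.18 and 4.02. In SD of the shifted counts, however, the knockout stood higher over all sequences, at 8.59 in the heterozygote and 9.78 in the knockout. Reads of 28 to 30 nt made up 34.2% and 40.9% of the libraries.

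**Figure D3:**
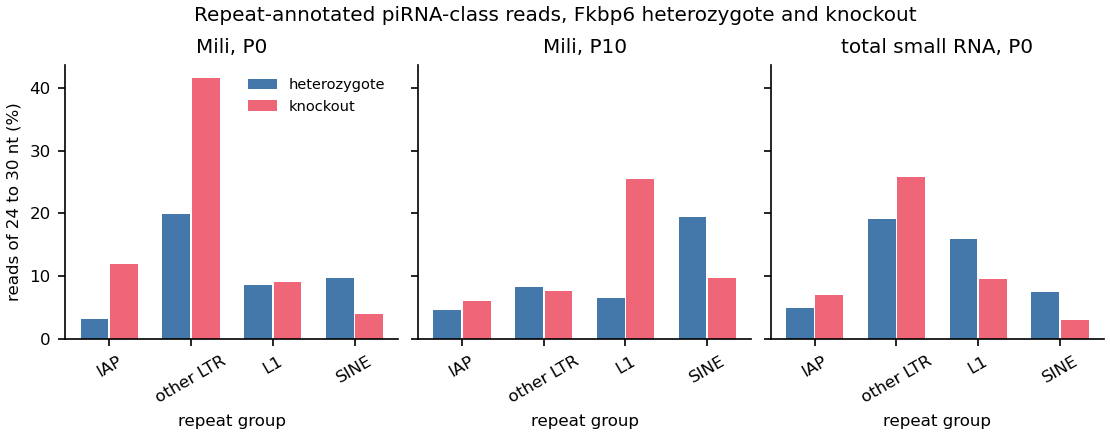
Percent of reads of 24 to 30 nt annotated as IAP, other LTR, L1 and SINE elements in Fkbp6 heterozygous and knockout libraries of Mili at postnatal days 0 and 10 and of total small RNA at day 0. Bars are single libraries, and IAP stood at 3.17% and 11.9% in Mili at day 0 while L1 stood at 6.54% and 25.5% at day 10.

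Total small RNA at postnatal day 0 showed how small RNAs of piRNA size differed, a class that here also held many fragments of structural RNAs. Fkbp6-annotated reads numbered 160 in the heterozygote and 27 in the knockout. Reads of 24 to 30 nt made up 40.6% of the heterozygous and 28.2% of the knockout library, and those of 28 to 30 nt, the Miwi2 size, 17.2% and 8.59% (log2 -1.002). Reads of 25 to 27 nt, the Mili size, made up 19.5% and 15.5% (log2 -0.33), a direction that turned when distinct sequences were counted (log2 0.10). L1 piRNAs were 1.67-fold lower (log2 -0.74, or -0.29 over distinct sequences), at 16.0% and 9.53% of the class, and SINE piRNAs 2.49-fold lower, at 7.50% and 3.01%. IAP piRNAs were 1.43-fold higher, at 4.89% and 6.99%, and other LTR piRNAs stood at 19.1% and 25.8%. Fragments of tRNA took 4.23% and 8.65% of the class, rRNA 4.42% and 8.13%, miRNA 6.39% and 11.1%, and snoRNA or snRNA 3.19% and 5.19%. Without these structural annotations the L1 difference was smaller. The muscle miRNA miR-1 was 12.3-fold lower in the same knockout library. Relative to the heterozygote, the knockout differed by -5.57 points in first-nucleotide U and by -5.56 points in A at nucleotide 10, or by -3.03 and -0.57 points over distinct sequences. These shares count the whole class, structural RNAs included. The ping-pong ratio was 2.68 in the heterozygote and 2.27 in the knockout, but 3.97 and 4.28 among IAP sequences.

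MicroRNAs of the same total small RNA libraries differed as well. miRNA-annotated reads made up 47.6% of the heterozygous and 58.8% of the knockout library. Among the 10 most abundant miRNAs of the heterozygote, miR-26a-2 was 3.68-fold and miR-99a 2.95-fold higher in the knockout, as shares of miRNA reads, and miR-199a-2 was 2.13-fold lower. The other 7 ranged from 1.43-fold lower (let-7f-1 and miR-103-1) to 1.34-fold higher (let-7i). Muscle miRNAs were far lower in the knockout, miR-1 by 12.3-fold (48398 and 4092 reads) and miR-133 by 18.4-fold (4050 and 229 reads). The gonadal miR-202 and miR-34c were 2.05-fold and 2.73-fold lower, and the blood miRNAs miR-142 and miR-451 were 1.60-fold and 1.59-fold lower. The interval of the blood miRNA miR-223 included no change (1.07-fold lower), the liver miRNA miR-122 had 63 and 28 reads, and the neuronal miR-124 had 8 and 7.

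The Tdrd1 comparison asked how loss of this Tudor-domain protein changed Mili piRNAs at embryonic day 18. Tdrd1-annotated reads numbered 40 in the heterozygote and 108 in the knockout, and they too check nothing about the genotype. Mili held longer piRNAs in the knockout, with 19.6% of reads at 28 to 30 nt against 8.47% in the heterozygote, 2.31-fold higher (log2 1.21, 1.21 to 1.21), while reads of 25 to 27 nt stood at 75.4% and 82.4%. Repeat groups differed little. Heterozygous and knockout shares were 6.95% and 7.94% for L1, 18.6% and 16.0% for other LTR elements, and 8.50% and 6.56% for SINEs. IAP piRNAs stood at 2.87% and 2.10% of reads (log2 -0.45), with no such difference over distinct sequences (log2 0.02). Of 13 annotations, none was at least 2-fold higher and 1, an IAP element, was at least 2-fold lower. The ping-pong ratio was 1.42 in the heterozygote and 1.24 in the knockout. It was 2.23 and 1.49 among L1 sequences and 2.57 and 2.15 among IAP sequences. In SD of the shifted counts, however, the knockout stood higher over all sequences, at 5.92 in the heterozygote and 7.77 in the knockout.

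Miwi2 was set beside Mili in the Tdrd1 heterozygote to see what each PIWI protein carried in the fetal testis. Miwi2 held 69.3% of its reads at 28 to 30 nt and Mili 8.47%. IAP elements made up 9.76% of Miwi2 and 2.87% of Mili piRNAs, 3.40-fold higher, and L1 12.9% and 6.95%, 1.85-fold higher. Other LTR elements made up 40.5% and 18.6%, 2.18-fold higher. IAPEz-int was 9.01-fold, RLTR10-int 7.201-fold and MMETn-int 7.14-fold higher in Miwi2, and the satellite GSAT_MM 10.4-fold higher. Of 38 annotations, 27 were at least 2-fold higher in Miwi2 and none at least 2-fold lower. SINE piRNAs stood at 7.13% in Miwi2 and 8.50% in Mili, and this order turned over distinct sequences (log2 0.09). First-nucleotide U was present in 72.5% of Miwi2 and 87.5% of Mili reads, and A at nucleotide 10 in 52.9% and 31.7%. Ping-pong pairs within Miwi2 exceeded the shifted mean by a ratio of 2.69, and pairs between Mili and Miwi2 by 2.17. In all, 24.2% of Mili piRNA reads had a sequence also found in Miwi2.

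**Figure D4:**
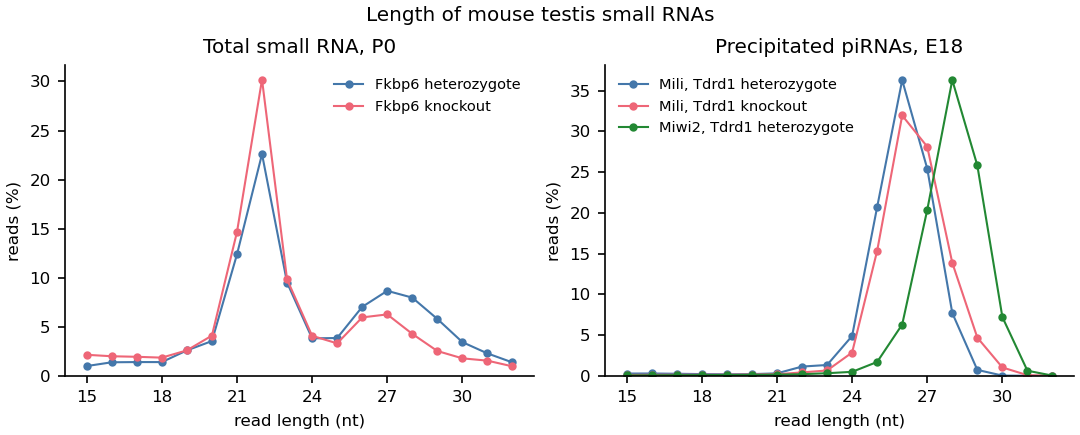
Percent of reads at each length in nt for total small RNA of Fkbp6 heterozygous and knockout testis at postnatal day 0, and for Mili of Tdrd1 heterozygous and knockout testis and Miwi2 at embryonic day 18. Lines are single libraries, and reads of 28 to 30 nt made up 17.2% and 8.59% of the total libraries, 8.47% and 19.6% of the Mili libraries and 69.3% of Miwi2.

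The polyA+ libraries asked which silkworm transcripts changed within 24 h of GA. Transposon transcripts were higher after GA as shares of annotated reads, LTR elements going from 2.72% to 5.26% and LINE elements from 2.10% to 3.61%. DNA elements went from 0.29% to 0.48% and SINEs from 0.29% to 0.40%. Of 79 transposon annotations with at least 20 reads, 72 had a log2 ratio above 0, 22 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.72. That median exceeded those of all 10000 random lists of gene models matched on expression, whose own median was -0.10. By class, the medians were 0.76 for 10 LTR annotations (percentile 99.9), 0.67 for 23 LINE annotations (percentile 100), 0.80 for 43 DNA annotations (percentile 100) and 0.43 for 3 SINE annotations (percentile 89.8). The ribosomal DNA-inserting element R1 was 4.67-fold higher (log2 2.22, 2.21 to 2.23), the telomeric element TRAS3-1 4.64-fold, MAG 4.29-fold and Pao-like-2 3.86-fold. Another entry of that telomeric element, TRAS3-2, was only 1.28-fold higher, and it held 568786 control reads against 1924 for TRAS3-1. The most abundant annotation, gypsy-Ty3-like, was 1.84-fold higher, and TRAS6 was 1.63-fold lower. Minor-strand reads within gene models were also more frequent in the GA library, at 5.09% and 7.97%, a difference of 2.87 points, and 78.0% of 7517 gene models had a higher minor-strand share. The dominant strand was chosen on the control library, which can raise the GA share by an amount that was not measured. Among transposon reads the minor-strand share was instead lower, at 23.6% in control and 18.2% after GA.

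**Figure D5:**
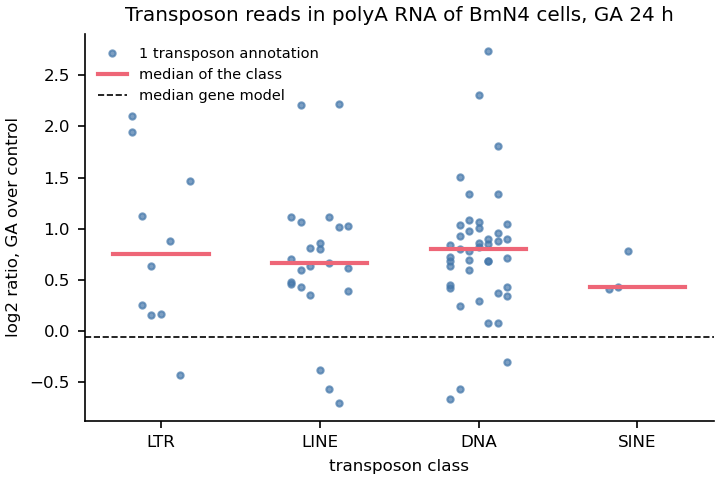
Log2 ratio of GA over control, scaled to annotated reads, for each of 79 transposon annotations by class, with class medians as bars and the median gene model as a dashed line. Class medians were 0.76 (LTR), 0.67 (LINE), 0.80 (DNA) and 0.43 (SINE).

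Gene models moved both ways after GA. Among 8917 with at least 100 reads in the library where they were higher, 1222 were at least 2-fold higher and 923 at least 2-fold lower, so that 57.0% of these were higher. Scaled to all reads, with the unannotated ones, the numbers were 1013 and 1237 (45.0% higher), and the median gene model moved from -0.05 to -0.20. BGIBMGA002259 went from 4 to 1148 reads, 327-fold higher, and BGIBMGA013746 from 0 to 405, at least 173-fold higher against a floor of 3 counts per library. BGIBMGA003781 went from 183 to 0 reads, at least 47.5-fold lower, and BGIBMGA009785 from 401 to 14, 21.6-fold lower. None of the 12525 gene model names could be tied to a gene symbol, so chaperone and piRNA-pathway genes were not assessed. Reads without an annotation made up 28.3% of the control and 35.2% of the GA library.

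Strand-specific polyA+ reads were also searched for stretches of piRNAs, to see whether transcripts of piRNA targets changed. Reads holding a 24-nt stretch antisense to a Siwi control piRNA went from 6.24% to 11.9% of all reads (log2 0.93), and those in the sense of a Siwi piRNA from 12.7% to 17.8% (log2 0.49). For Ago3 control piRNAs, antisense reads went from 5.64% to 10.8% (log2 0.93) and sense reads from 14.3% to 18.9% (log2 0.40). These reads overlap those of the transposon annotations and are not a separate line of evidence.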

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

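Of the tests in this part, those of single abundant IAP sequences, of other piRNAs leaving the denominator, of reads carried over from a by-product library, of scaling, of the number of ADH sequences, of a single sequencing run and of double-stranded DNA as the main source were chosen only after the results were seen.

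LTR piRNAs of Mili were more frequent in the Fkbp6 knockout at postnatal day 0, IAP by a log2 ratio of 1.91. A few abundant IAP sequences were not the source, since the ratio over distinct IAP sequences was 1.84. The log2 ratio of IAP exceeded that of L1 by 1.84, which argued against a loss of other piRNAs that spared L1. A loss that included L1 would give the same gap, so it stays open. The shares of SINE, unannotated and other piRNAs were lower in the knockout (log2 -1.27, -0.78 and -0.92), and shares alone cannot separate such a loss from a gain of LTR piRNAs. Miwi2 piRNAs caught in the Mili precipitate would lengthen the IAP reads, yet the 28 to 30 nt share of IAP reads was 14.4% in the heterozygote, 20.4% in the knockout and 72.3% in Miwi2, 10.4% of the way, which argued against them as the whole source. Reads with a sequence also found in Miwi2 did go from 21.9% to 37.8%, so a part from Miwi2 stays open. A change of Mili loading with loss of Fkbp6 may explain the pattern, and this was not tested. A difference between the animals of the single libraries stays open as well.

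In HA-tagged wild-type Ago3, 16-nt sequences with their complement at nucleotides 11 to 26 of Ago3 piRNAs were more frequent after GA than in control cells, a difference not detectable at this depth in ADH or R to K. Carry-over from by-product library 1, which was in another pool, was argued against by its 100 most abundant sequences, which held 27.8% of 16-nt reads there and 2.14% in HA-Ago3 after GA, 7.71% of that share. The ordinary Ago3 and Siwi precipitates, which shared the pool of by-product library 1, were not tested for carry-over. Neither were the ADH libraries, which shared the pool of by-product library 2. For too few sequences in R to K after GA, 10000 draws of 663 wild-type sequences, its number, had a lowest share of 26.9985%. For ADH, draws of 559 had a lowest share of 25.8%. These draws took most of the 928 wild-type sequences without replacement, so they had to stay near 30.6% and decide little. The counting intervals after GA lay apart, at 27.7 to 33.6% in wild type, 12.0 to 17.8% in ADH and 3.31 to 6.56% in R to K. These intervals argue against too few sequences after GA. The mutant controls were not drawn, and held 426 (ADH) and 180 (R to K) sequences against 154 in the wild-type control. A requirement for slicing and for the arginines could explain the pattern, as an untested hypothesis, because construct and sequencing pool cannot be told apart.

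Transposon annotations were higher in the polyA+ library after GA, by a median log2 ratio of 0.72. Scaling as the source was argued against by the median of gene models matched on expression, which a scaling factor would move alike and which the transposon median exceeded by 0.82, and a single sequencing run by a median of 0.72 in the lower of the 2 runs. DNA or antisense RNA in the GA library stays open, since the minor-strand share of gene model reads was higher by 2.87 points, above a bound set beforehand at 2. The choice of strand on the control library can add to that difference. Double-stranded DNA as the source of most added transposon reads was argued against, with 0.15 reads added on the minor strand for each on the dominant strand. A response of transposons to GA may also account for the difference and was not tested.

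Effects of the Fkbp6 knockout on Mili pointed in opposite directions at the 2 ages for some repeats, and the difference between ages was not tested. Other LTR elements had log2 ratios of 1.06 at postnatal day 0 and -0.13 at day 10, but over distinct sequences these were 0.77 and 0.0039 and no longer opposite. L1Md_T had -0.25 and 2.72, and MTA_Mm-int 1.59 and -0.24. In mouse, where no comparison used the placement of 16-nt sequences, these lay opposite nucleotides 11 to 26 of piRNAs of their own library more often than at any other start in Mili of the knockout at postnatal day 10 (6.27%, highest other 5.19%) and in total small RNA of the knockout (7.43%, 5.04%) and the heterozygote (10.7%, 7.87%). In the other 5 Mili libraries another start had a higher share of distinct sequences. At day 0 the shares were 2.14% against 4.38% in the heterozygote and 2.31% against 2.74% in the knockout. They were 2.30% against 2.92% in the heterozygote at day 10, and 2.89% against 3.97% and 3.37% against 4.20% in the Tdrd1 heterozygote and knockout. In Miwi2 the share was 14.0%, with 13.8% at the highest other start. Weighted by reads, nucleotides 11 to 26 did stand highest in the day 0 knockout (3.13%, highest other 2.88%) and the Tdrd1 heterozygote (5.23%, 4.40%). Another start stayed higher by reads in the Fkbp6 heterozygotes at both ages, in the Tdrd1 knockout and in Miwi2 (21.7% against 23.8%). The 16-nt share of reads itself differed within pairs, at 0.0408% in heterozygous and 0.191% in knockout Mili at day 0 (log2 2.23), 0.0614% and 0.109% at day 10 (log2 0.82), 1.38% and 1.996% in total small RNA (log2 0.53), and 0.287% and 0.128% in the Tdrd1 pair (log2 -1.16). Reads under 15 nt of by-product library 2 ended in GATC and the barcode of the library in 76.2% of cases, against 0.0005% in the control short RNAs.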

How the results depend on the processing

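Of the alternatives here, those for annotation groups, for size classes over distinct sequences, without miRNA-annotated reads or among reads of 15 nt and longer, and for polyA+ scaling to all reads or to 1 sequencing run were chosen after seeing the data. Over 139 results, 422 alternative values were computed. Of these, 113 stayed within the range set for the main value, 292 moved beyond it and 17 reversed direction. That range was the counting interval, except for the by-product pair (1 SD), ping-pong ratios (from the SD of the shifted counts) and numbers of gene models (a fixed fold). Of 189 values that were differences, 172 had the sign of the main value. Except where stated, the cause was not tested. Counting intervals are narrow at these depths, so small shifts as well as large ones lie beyond them. With 1 library in all groups but 1, spread between animals or cultures limits the results and could not be estimated. No paired analysis was possible because no label pairs the libraries beyond sharing a pool. Restricting reads to exact genome matches and counting 5′-end overlaps on a genome were planned and not run, since no genome was given.

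Counting distinct sequences in place of reads turned several differences. First-nucleotide U became 0.90 points for Mili at postnatal day 10, -0.13 for Siwi after GA and -0.39 for R to K after GA. A at nucleotide 10 became 1.78 points for HA-Ago3 after GA. Log2 ratios became 0.0039 for other LTR elements in Mili at day 10, 0.017 for IAP in the Tdrd1 pair, 0.090 for SINEs in Miwi2 over Mili, -0.020 for LTR elements in Siwi after GA, -0.050 for LINE elements in Ago3 after GA and -0.34 for tRNA in HA-Ago3 after GA. Without structural RNA annotations, LINE elements in Siwi after GA became -0.0052. Limits of 25 to 28 nt turned A at nucleotide 10 to -0.17 points for Mili at day 10 and -0.33 for the Tdrd1 pair. Among reads not beginning with U it became -3.99 points for the Tdrd1 pair and 3.17 for HA-Ago3 after GA.

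For total small RNA at postnatal day 0, the log2 ratio of reads of 25 to 27 nt was -0.30 among reads of 18 nt and longer, -0.63 per read of 21 to 23 nt, 0.10 (reversed) over distinct sequences and -0.0021 without miRNA-annotated reads. That of 28 to 30 nt was -0.97, -1.30, -0.63 and -0.66 in that order. In the Tdrd1 pair it was 1.20 among reads of 18 nt and longer and 1.12 over distinct sequences. IAP in Mili at day 0 had 1.84 over distinct sequences and 1.69 with at least 2 reads, other LTR elements 0.77 and 1.20, and L1 0.57 and -0.44 (reversed). L1 at day 10 had 0.83 and 2.20, and 1.93 without structural RNAs. In total small RNA L1 had -0.29, -1.25 and -0.45 under these 3 settings.

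The Ago3 minus Siwi difference in first-nucleotide U was -48.5 points at 25 to 28 nt and -28.9 over distinct sequences. That in A at nucleotide 10 was 47.4 and 28.8 points, and 40.0 among reads not beginning with U. For Mili in the Fkbp6 pair at day 0, A at nucleotide 10 differed by 7.39, 4.01 and 17.3 points under the same settings.

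Ping-pong ratios weighted by reads were 2.66 and 3.95 for Mili at day 0, 19.3 and 13.6 at day 10 (heterozygote, knockout), and 48.9 and 26.3 for Siwi with Ago3 (control, GA). With at least 2 reads per sequence they were 2.41 and 2.901, 7.46 and 4.5996, and 5.90 and 5.85. Thinned to equal depth they were 4.96 and 3.41 at day 10 and 4.37 and 4.26 for Siwi with Ago3.

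Placement at nucleotides 11 to 26 is given for the by-product mean, control short RNAs, HA-Ago3, ADH and R to K after GA. Weighted by reads it was 65.9%, 19.0%, 24.7% and, for R to K, 7.66%. With 15-nt reads it was 13.8%, 2.61%, 7.83% and, for ADH, 10.05%, and with 17-nt reads 20.96%, 8.14%, 6.81% and 5.74%. With at least 2 reads it was 35.4%, 26.6%, 20.1% for ADH and 6.75% for R to K. Against Siwi control piRNAs it was 15.8%, 9.42%, 20.8% and 10.02%, and against Siwi GA piRNAs 17.5%, 9.97%, 23.4%, 10.02% and 2.87%. Leaving out either by-product library gave 22.6% to 24.4% for placement and 40.3% to 89.6% for the 16-nt share. Over distinct sequences the log2 ratio of the 16-nt share was 2.40 for HA-Ago3, 0.033 for ADH and 1.95 for R to K.

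Gene models at least 2-fold higher after GA numbered 1222 in the main count, 2080 with at least 20 reads and 2863 with no minimum, and those lower numbered 923 in the main count and 1822 with no minimum, as more gene models were counted. Scaling to all reads gave 45.0% higher in place of 57.0%. Under that scaling the median log2 ratios were 0.61 for LTR, 0.52 for LINE, 0.28 for SINE and 0.58 for all transposon annotations. Runs 1 and 2 alone gave 0.83 and 0.69 for LTR and 0.61 and 0.73 for LINE, run 1 alone gave 0.48 for SINE, and DESeq2 size factors gave 0.64 for LINE.

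For polyA+ reads matching piRNAs, log2 ratios with 20-nt stretches were 0.44 and 0.89 (Siwi sense, antisense) and 0.37 and 0.90 (Ago3). With piRNAs of at least 2 reads they were 0.84, 1.00, 0.64 and 1.01. Thinned to equal depth, shared reads were 77.1% for Siwi in Ago3, 28.8% for heterozygous in knockout Mili at day 0 and 22.7% for Mili in Miwi2.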

Other observations

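Of the tests in this part, that of by-products lying next to Siwi piRNAs was chosen only after the result was seen, and that of annotation groups behind the share of A at nucleotide 10 was written before.

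Siwi and Ago3 control piRNAs held many elements at different frequencies, while LINE annotations together made up 15.3% of Siwi and 14.9% of Ago3 reads and LTR annotations 16.99% and 19.06%. In Ago3, DNA elements were 1.81-fold lower, tRNA 14.1-fold lower and gene models 1.68-fold higher, all counted over reads. Over distinct sequences the tRNA difference vanished, at 0.187% in Siwi and 0.193% in Ago3. Of 41 annotations that held at least 0.5% of reads in either library, 11 were at least 2-fold more frequent in Ago3, 18 at least 2-fold less frequent, and the rest within 2-fold. Fragments of the glutamate tRNA Glu(TTC) made up 2.15% of Siwi and 0.026% of Ago3 piRNA reads, 84.3-fold lower in Ago3, and the mariner element BMMAR3 was 8.002-fold lower. Higher in Ago3 were a copy of the LINE R1 (bm_1093_LINE_R1, 64.6-fold), the telomeric LINE TRAS3-2 (7.29-fold) and the LTR element Yamato (4.66-fold). These names were chosen after their values were seen.

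Piwi populations in the mouse overlapped to different degrees. At postnatal day 0, 37.8% of Mili piRNA reads of the Fkbp6 knockout had a sequence also found in the fetal Miwi2 library, and 21.9% of those of the heterozygote. Thinned to equal depth within each pair, at 3948922 and 3282578 reads, the shares were 33.6% and 17.6%. Between heterozygous and knockout Mili, 62.4% of heterozygous reads were shared at postnatal day 10 and 50.1% in the Tdrd1 pair at embryonic day 18.

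Part of the 16-nt by-products of Ago3 ended where Siwi piRNAs began. On the deposited coordinates, the nucleotide after the end of the by-product was the 5′ end of a Siwi control piRNA on the same strand for 45.1% of 16-nt reads in by-product library 1 and 42.9% in library 2, against at most 10.4% and 10.5% at any of 12 other offsets. In library 1 the share was 4.35 times the highest other offset. Of distinct 16-nt sequences, 13.7% and 15.7% lay so, against at most 5.74% and 6.12% at another offset. The same position was the 5′ end of an Ago3 control piRNA for 31.6% and 29.4% of reads. For Siwi control piRNAs the share was 12.9% of reads in the control short RNAs of Ago3, against at most 5.78%. For these by-products, the by-product and a Siwi piRNA may be neighbouring parts of 1 cut RNA, a hypothesis found and tested on the same libraries.

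A shift between repeat groups was tested as the source of the higher share of A at nucleotide 10 in knockout Mili at postnatal day 0. Reweighting the heterozygous shares to the group make-up of the knockout gave 1.18 of the 7.72 points, or 15.2%, and the same shift at the knockout's shares of A within each group gave 3.94 points, or 51.01%. A shift between these groups alone was thus argued against, and from 3.78 to 6.54 points lay within the groups. The groups were coarse, and log2 ratios of single other LTR names ranged from -0.99 to 2.87. A shift between families inside a group counts as within it and stays open.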
